A study of Mus musculus with 9 samples.

How the data were processed

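Gene expression was measured in the hippocampus of C57BL/6 mice aged 12 to 14 weeks on an Affymetrix mouse gene array, with 9 arrays in 3 groups of 3. The groups were control mice, mice with a surgically induced tibia fracture, and mice given Maresin 1 before the same surgery. Maresin 1 is a lipid mediator that macrophages make from docosahexaenoic acid. Hippocampi were taken 72 h after surgery, 6 µg of total RNA was used per array, and the titles name the 3 arrays of a group as biological replicates. Sample groups were taken from the titles alone.

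The authors made the deposited values with Affymetrix Expression Console, per the submitters' processing notes, and its version and algorithm are not given in the sources used here. The unit of the deposited table is intensity, a linear signal per probe set, for 35556 probe sets in each array. The median signal ranged from 54.1 to 100 between arrays, a 1.85-fold range, and 92 to 244 probe sets per array stood at exactly 0. Control replicate 1 had the highest median and the fewest zeros. The curves of the 9 arrays also differed in shape, so the deposited signals carry no visible normalization between arrays. Arrays have no read depth, and their number, 3 per group, limits the precision.

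The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That plan assumed log2 values normalized by the authors and took them as they stood. The values turned out to be linear and unequal between arrays. They were therefore quantile normalized, 16 was added, and log2 was taken. This change was made after the signal distributions had been seen and before any model was fitted. The plan read literally, with log2 of the deposited signals, called 42 genes between surgery and control, 0 between Maresin 1 and surgery, and 43 between Maresin 1 and control, with 41 lower than in control in both comparisons with control. The planned centring of each array was run on log2 values first, and scaling of the linear values to one median was added afterwards.

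Of the probe sets, 21218 name 1 gene, 1881 name several genes and 12457 are not listed with a gene in the probe table used. The gene identifiers of 21185 probe sets of 1 gene matched the gene table. The probe set with the highest mean over all arrays stood for each of the 1386 genes with over 1 probe set, which left 18820 genes. As a guide to background, the 95th percentile of the mean level of 990 olfactory receptor genes, which the brain hardly expresses, was 5.86 on the log2 scale. A total of 13363 genes, 71.0%, lay above it. No filter on dim genes was applied.

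Differences between groups were tested with limma 3.58.1 in R 4.3.3, with 1 linear model over all 9 arrays, no covariate and a variance prior that follows the mean level. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Errors of differences are standard errors (SE) of that model, errors of group levels are standard deviations (SD), and n is 3 in each group. Gene lists were tested with camera, two-sided, with a preset correlation between genes of 0.01, on the 54 lists with at least 5 genes measured. The 162 tests of the 3 comparisons were adjusted together. Beside it stand camera with a correlation estimated for each list, fry, and the number of list genes that pass when p is adjusted over the list alone. A list score is the mean over its genes of the difference of an array from the mean of all 9 arrays.

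How far Maresin 1 turned the surgery values back was measured as a slope across genes. Each surgery array was held out in turn, so that the surgery effect and the Maresin 1 effect shared no array. The pipeline was tested on simulated data with 50 changed genes of each size, from 0.3 to 2 on the log2 scale in one data set. Noise was independent between genes and had the same spread in each group. The large changes ease the adjusted threshold, so data with fewer of them would give lower shares. For surgery against control, 26% of genes changed by 0.3 on the log2 scale were called, 68% at 0.5 and 98% at 1, with 7 unchanged genes called. For slopes of 0, -0.5 and -1 put into simulated data with surgery effects of SD 0.3 in all genes, the method returned -0.011, -0.422 and -0.842. The list test was run on 100 simulated data sets with no group effect that kept the correlation between genes found within groups, pooled over the 3 groups, and the report gives the result.

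Named genes follow a fixed rule. Its opening part takes called genes whose groups do not overlap, up to 12 in each direction by size, without gene models, microRNA, snoRNA and olfactory or vomeronasal receptor genes. It is filled to 24 by the smallest p among genes with a log2 difference of at least 0.3 and a mean above the median gene. Added to these are up to 4 genes with the smallest p from each list, with called members up to 10, and a fixed set of inflammatory, glial and lipid mediator genes. In that set C3 has no probe set of 1 gene and was not analysed here. Alternatives covered normalization, the added constant, filters, the variance prior, array weights, a replicate block, the choice of probe set, thresholds, other tests and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.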

Results

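The data comprise 9 array profiles of mouse hippocampus, 3 from control mice, 3 from mice taken 72 h after tibia fracture surgery and 3 from mice given Maresin 1 before that surgery. Signals of 18820 genes were compared. The series title names the question, whether Maresin 1 lowers neuroinflammation in a model of the cognitive disorders that follow surgery.

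Transcripts of the choroid plexus, the epithelium that secretes cerebrospinal fluid, set 2 control arrays apart from the other 7. The deposited signal of Ttr, which encodes the thyroid hormone carrier transthyretin, was 5034 in control replicate 2 and 6065 in control replicate 3, against 228 in control replicate 1. It lay between 58.7 and 222 in the surgery arrays and between 207 and 302 in the Maresin 1 arrays. Kl, which encodes the ageing-linked membrane protein klotho, stood at 891 and 1319 in these 2 controls and at 339 in control replicate 1. All 21 measured genes of the choroid plexus list were higher in both controls 2 and 3 than in control 1. The main axis of variation held 33.9% of the variance between arrays, and 16 of the 25 genes with the largest weight on it belonged to this list.

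**Figure D1:**
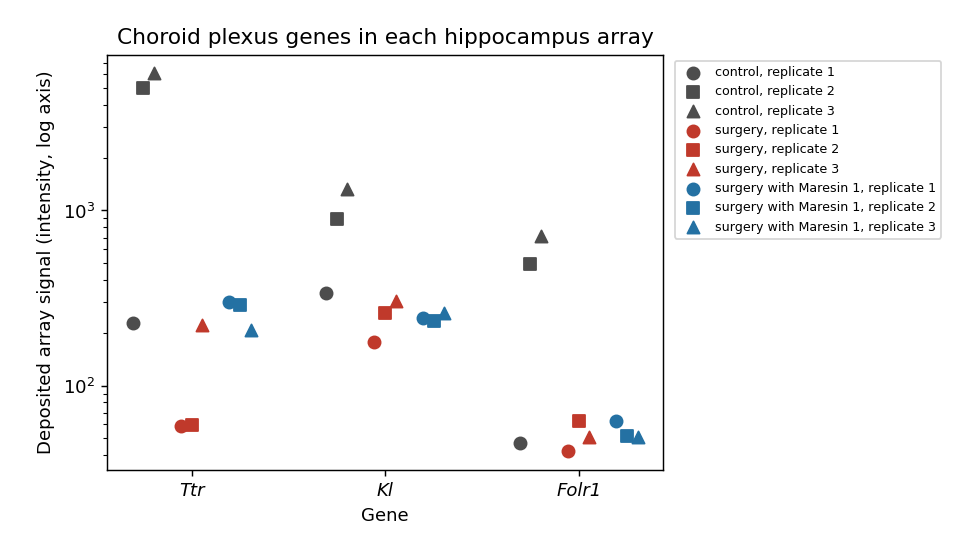
Deposited signal (intensity, log axis) of the choroid plexus genes Ttr, Kl and Folr1, with 1 point per array, coloured by group and shaped by replicate number. Control replicates 2 and 3 lie above the other 7 arrays for each gene, as for Ttr at 5034 and 6065 against at most 302.

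Surgery was compared with control to ask what fracture surgery leaves in the hippocampus after 72 h. Genes of blood vessels stood among those with the smallest p, though none passed the adjusted threshold. Acta2, the smooth muscle actin of the vessel wall, was at 8.83 ± 0.02 (SD, n = 3) after surgery and 8.04 ± 0.15 in control, a 1.73-fold difference (log2 0.79, SE 0.12, adjusted p = 0.261). The endothelial adhesion receptor Adgrl4 differed by 1.5-fold (log2 0.59, SE 0.11), and Flt1, a receptor for vascular endothelial growth factors, by 1.41-fold (log2 0.49, SE 0.10). Podxl, a sialomucin of endothelial surfaces, differed by 0.46, Adgrf5 by 0.41, the smooth muscle light chain Myl9 by 0.40 and the chemokine Cxcl12 by 0.37. The clock repressor Ciart differed by 0.60 and the interferon-induced Ifit3 by 0.48. Lower values without overlap included those of the retinol receptor gene Stra6 (-0.53), the transcription factor gene Creb5 (-0.43), the kinase gene Prkcq (-0.42) and the splicing factor gene Srsf5 (-0.32). Adjusted p ran from 0.261 to 0.640 over the 24 genes named by the rule. Against control replicate 1 alone these lower values stood at -0.13, -0.45, -0.20 and -0.44, and Srsf5 at -0.17 with each array scaled to one median.

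The endothelium list was higher after surgery by a mean log2 of 0.27, with 15 of its 17 measured genes higher. Its score was 0.10 ± 0.02 (SD, n = 3) after surgery and -0.17 ± 0.01 in control, with no overlap between arrays. The camera test gave adjusted p = 4.3e-10, and adjusted p = 0.955 with an estimated correlation. Adjusted over the list alone, 9 genes passed, among them Flt1, the junction protein gene Pecam1 (0.46), the drug efflux pump Abcb1a (0.38) and the organic anion carrier Slco1a4 (0.33), and 0 passed over all genes. Pericyte and smooth muscle genes were higher by 0.22, 14 of 15 of them, with adjusted p = 5.4e-06 and adjusted p = 0.955 with an estimated correlation. Acta2, the smooth muscle myosin Myh11 (0.50) and the pericyte regulator Rgs5 (0.32) passed when adjusted over the list alone, and 0 over all genes. Of 4 measured red cell genes, too few for a list test, Alas2, of haem synthesis in red cells, differed by 0.95 (SE 0.25, adjusted p = 0.63) without overlap and was highest in surgery replicate 2, and Slc4a1, Epb42 and Fech differed by 0.16, 0.11 and 0.06.

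Interferon response genes were higher after surgery by a mean of 0.23, 20 of 23 of them, with adjusted p = 7.7e-07 and adjusted p = 0.955 with an estimated correlation. Of these 11 passed when adjusted over the list alone, 10 higher and 1 lower, and 0 over all genes. Gbp2, a guanylate-binding protein, differed by 0.77, Ifit3 by 0.48, Gbp7 by 0.43 and Oasl2 by 0.40, while Ifi27 was lower at -0.35. Reactive astrocyte genes were higher by a mean of 0.20, 28 of 33, with adjusted p = 0.000331 and adjusted p = 0.955 with an estimated correlation. Osmr, the oncostatin M receptor, differed by 0.59 and alone passed when adjusted over the list alone, and 0 genes passed over all genes. Surgery replicate 2 had the highest score of the 9 arrays for both lists, 0.25 for interferon and 0.23 for reactive astrocytes. Homeostatic microglia genes were higher by 0.10, 16 of 18, with 0 passing when adjusted over the list alone (adjusted p = 0.0205, and adjusted p = 0.973 with an estimated correlation), and the call was lost without control replicate 1 or 3 or surgery replicate 2.

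Of the inflammatory genes, Il6 differed by 0.14 (SE 0.10), Il1b by 0.05 (SE 0.11) and Tnf by 0.11 (SE 0.13), and these cytokine genes lay below the olfactory receptor level of 5.86 in all 9 arrays. The chemokine gene Ccl2 differed by -0.25 (SE 0.14), and by -0.38 to 0.03 over 18 alternatives. Gfap, the astrocyte filament gene, differed by 0.10 (SE 0.07), and the microglial genes Aif1, Cd68 and Itgam by 0.08, 0.08 and 0.29. Itgam, the integrin subunit of complement receptor 3, showed no overlap between groups (SE 0.09, adjusted p = 0.68). Lcn2, the iron-scavenging acute phase protein lipocalin 2, differed by 1.85 (SE 0.80, adjusted p = 0.781) from a control level of 5.15, under the olfactory receptor level, so that the size of the difference depends on the added constant. Its deposited signals after surgery were 21.5, 772 and 56.8, with a log2 difference of 0.65 without surgery replicate 2. The cytokine list (mean 0.06, adjusted p = 0.348) and the NF-kB and inflammasome list (0.10, adjusted p = 0.0913) were not called, with 1 gene each passing when adjusted over the list alone, Cxcl12 and Tnfaip3. Tnfaip3, an inhibitor of NF-kB signalling, differed by 0.46 (SE 0.09), and Casp1 by 0.36 and Tlr2 by 0.23 at mean levels under the olfactory receptor level, each without overlap. Fkbp5, a chaperone gene induced by glucocorticoids, differed by 0.27 (adjusted p = 0.683), and by 0.12 to 0.40 over 18 alternatives.

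Choroid plexus genes were lower than in control by a mean of -1.86, all 21 of them, with adjusted p = 2.0e-23 and adjusted p = 0.955 with an estimated correlation. Adjusted over the list alone 18 passed, and 0 over all genes. Ttr differed by -4.09 (SE 0.99) and the bone morphogenetic protein antagonist Sostdc1 by -1.99, while control replicate 1 had a list score of -0.78, below the -0.68 to -0.57 of the surgery arrays. Against control replicate 1 alone the mean difference of the list was 0.14.

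In all, limma called 0 of 18820 genes between surgery and control, against 1168 at an unadjusted p under 0.05, 734 higher and 434 lower, where 941 are expected by chance. Of those that also differed by 1.5-fold, 13 were higher and 59 lower. Groups did not overlap for 11.5% of genes, against 10% by chance. Camera called 10 of 54 lists, fry 0 and the estimated correlation 0, and in 100 simulated data sets with no group effect camera called a median of 11.5 lists (4 to 23). The number of calls was thus no higher than in those data, which tests no single list. The simulation gave all groups the pooled residuals, while choroid plexus scores varied mainly among controls (SD 1.74, against 0.057 after surgery). Without control replicate 1 the remaining controls are those with high choroid plexus signal, and the count of genes was 169, 150 of them lower after surgery. How far that signal accounts for the lower genes was not tested. Without surgery replicate 1 the count of lists was 17.

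**Figure D2:**
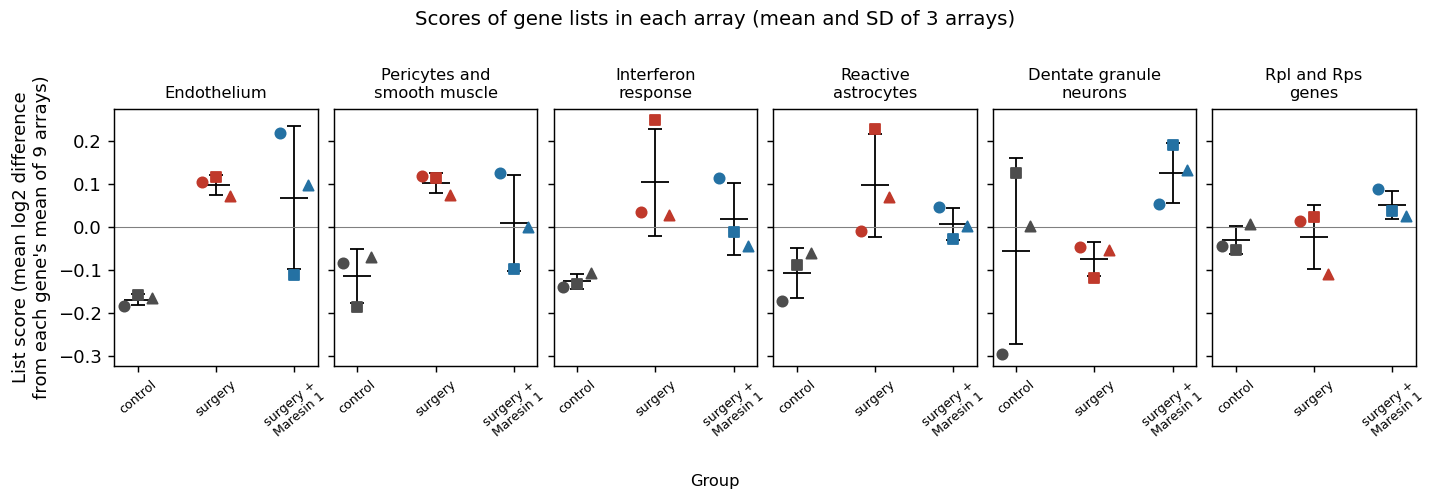
List scores (mean log2 difference from the mean of each gene over 9 arrays) for 6 gene lists, with 1 point per array shaped by replicate number and bars for the mean and SD of 3 arrays per group. Control arrays lie lowest for the endothelium list, at -0.18 to -0.16, and Maresin 1 arrays spread from -0.11 to 0.22.

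Maresin 1 with surgery was compared with surgery alone to ask what the treatment changed in operated mice. No gene passed the adjusted threshold. Synpo, the spine apparatus protein synaptopodin, was 1.25-fold lower (log2 -0.33, SE 0.06, n = 3 per group, adjusted p = 0.617), Vgf, a neuropeptide precursor gene, differed by -0.33 (SE 0.08) and the presynaptic gene Rims4 by -0.34 (SE 0.10). The transcription factor gene Etv5 differed by -0.33 and Tmem121b by -0.30. On the higher side stood the cation channel Trpc6 (0.49, SE 0.11), the nuclear RNAs Lncpint (0.50) and Malat1 (0.40), the myelin gene Opalin (0.34) and Fabp7 (0.37), a fatty acid carrier of radial glia and astrocytes. Over 18 alternatives their lowest values were 0.37 for Trpc6, 0.36 for Lncpint, 0.21 for Malat1 and Opalin, and 0.20 for Fabp7. Adjusted p ran from 0.617 to 0.859 over the 24 genes, and the groups did not overlap for 19 of them.

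Dentate granule neuron genes were higher with Maresin 1 than after surgery alone by a mean of 0.20, 16 of 17, with adjusted p = 4.3e-10 and adjusted p = 0.955 with an estimated correlation. Trpc6 and the Rac and Cdc42 exchange factor gene Dock10 (0.29) passed when adjusted over the list alone, and 0 over all genes. Prox1, which sets granule cell identity, differed by 0.24. Dentate granule scores in the control arrays ran from -0.29 to 0.13, a wider span than the difference. The CA1 pyramidal neuron list had a mean of -0.08, 9 of 12 lower, with no overlap between arrays, and was not called (adjusted p = 0.12). Ribosomal protein genes were higher by 0.07, 68 of 83, with 0 passing when adjusted over the list alone (adjusted p = 1.3e-14, and adjusted p = 0.955 with an estimated correlation). Surgery replicate 3 carried much of this, as these genes scored 0.015, 0.025 and -0.107 in the surgery arrays and 0.089, 0.038 and 0.027 with Maresin 1. When each array was centred on its median their mean was -0.06, against -0.09 for the median of all genes, and the call was lost (adjusted p = 0.343). Myelinating oligodendrocyte genes were higher by 0.12, 14 of 15, with 0 passing when adjusted over the list alone (adjusted p = 0.000109, and adjusted p = 0.973 with an estimated correlation). Their mean was -0.01 when arrays were centred, and the call was lost (adjusted p = 0.0783). Scores of this list overlapped, at 0.13, -0.14 and -0.09 in the surgery arrays and 0.14, 0.14 and -0.02 with Maresin 1.

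All 13 genes of the border macrophage list, cells of the meninges and perivascular spaces, were lower with Maresin 1, by a mean of -0.17. Of these genes, 6 had a mean above the olfactory receptor level. List scores were 0.069, 0.131 and 0.040 in the surgery arrays and 0.033, -0.146 and -0.158 with Maresin 1. In the control arrays they ran from -0.11 to 0.10, a wider span than the difference. The carbonyl reductase gene Cbr2 differed by -0.41 and the mannose receptor gene Mrc1 by -0.25, with 0 genes passing when adjusted over the list alone (adjusted p = 0.00122, and adjusted p = 0.955 with an estimated correlation). Meningeal and vascular fibroblast genes were lower by -0.19, 17 of 20, among them the collagen gene Col1a2 at -0.32, with 0 passing when adjusted over the list alone (adjusted p = 0.00547, and adjusted p = 0.973 with an estimated correlation), a call lost without Maresin 1 replicate 2 or 3. Small nucleolar RNA genes were lower by -0.14, 39 of 56, with 1 passing when adjusted over the list alone (adjusted p = 0.0077, and adjusted p = 0.973 with an estimated correlation), a call lost without surgery replicate 2 or Maresin 1 replicate 3.

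Of the inflammatory genes, Il6 differed by -0.22 (SE 0.10, adjusted p = 0.859) below the olfactory receptor level, Il1b by -0.08, Tnf by -0.07, Ccl2 by -0.03 and Lcn2 by -0.20 (SE 0.80). The Lcn2 value was -0.96 without surgery replicate 1, 1.00 without surgery replicate 2 and 0.46 without Maresin 1 replicate 1. Gfap differed by 0.09 and Itgam by -0.05, while Casp1 (-0.34) and Tlr2 (-0.24) were lower without overlap at low levels (adjusted p = 0.859). Casp1 and Tlr2 had stood higher after surgery than in control, but both comparisons share the surgery arrays. Simulated data with no effect gave a correlation of -0.50 between the comparisons across genes, so opposite signs do not by themselves show a reversal. The interferon list had a mean of -0.08 (adjusted p = 0.226), reactive astrocytes -0.09 (0.18), NF-kB and inflammasome -0.06 (0.257), cytokines -0.06 (0.490) and endothelial activation -0.12 (0.0813), and none of these lists was called. Lgr6, a G protein-coupled receptor for Maresin 1, differed by 0.03 (SE 0.10), and Rora, a nuclear receptor that binds Maresin 1, by 0.01 (SE 0.07).

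Between Maresin 1 and surgery limma called 0 genes, against 1065 at an unadjusted p under 0.05, 368 higher and 697 lower. Groups did not overlap for 13% of genes, against 10% by chance. Camera called 8 lists, fry 0 and the estimated correlation 0, while simulated data with no effect gave a median of 13 lists (4 to 26). That simulation pooled the residuals of all groups. The choroid plexus genes that lead them varied mainly between controls (score SD 1.74, against 0.057 in each group of operated mice). It therefore does not give the count for arrays of operated mice alone. Camera called 16 lists without surgery replicate 1 and 13 without Maresin 1 replicate 2.

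Maresin 1 with surgery was compared with control to ask what remained different from mice without surgery. Here 16 genes passed the threshold, 13 higher and 3 lower. Pros1, which encodes the anticoagulant protein S, rose 1.58-fold (log2 0.66, SE 0.10, n = 3 per group, adjusted p = 0.0382), from 6.93 ± 0.15 (SD) to 7.58 ± 0.13. Cxcl12, a chemokine of vessels and neurons, rose 1.38-fold (log2 0.47, SE 0.07) and the monocarboxylate transporter Slc16a1 1.35-fold (log2 0.43, SE 0.07). Sesn1, a stress-induced inhibitor of growth signalling, rose by 0.44 (SE 0.06). Eapp, which encodes a protein bound to E2F factors, had the smallest adjusted p, 0.0270 (log2 0.43, SE 0.05).

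Bpnt2, a Golgi phosphatase gene, rose by 0.51, the mitochondrial import gene Mtx2 by 0.50, Ciao2a of iron-sulphur cluster assembly by 0.42, the microtubule organiser Mzt1 by 0.42, Chic2 by 0.40 and the vesicle coat GTPase Sar1b by 0.36. Psmd14, which encodes a proteasome subunit, rose by 0.36, and Psma1, named after its values were seen, by 0.33. The genes that fell were Zfp580 (-0.53, SE 0.08), Tmem121b (-0.44, SE 0.06) and the ubiquitin ligase gene Rnf208 (-0.32, SE 0.05). After surgery alone the smallest adjusted p of the 16 was 0.384. Their surgery differences had the same sign, at a median ratio of 0.547 to the Maresin 1 differences, but both share the control arrays, and simulated data with no effect gave a correlation of 0.499 between them across all genes. At an adjusted p under 0.10 there were 91 genes, 58 higher and 33 lower. Among the lower ones named by the rule, at adjusted p from 0.0696 to 0.0886, stood Cuta (-0.44), Vgf (-0.43), the synaptic gene Prrt1 (-0.40), the calcium channel gene Cacna1i (-0.33) and Synpo (-0.32).

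**Figure D3:**
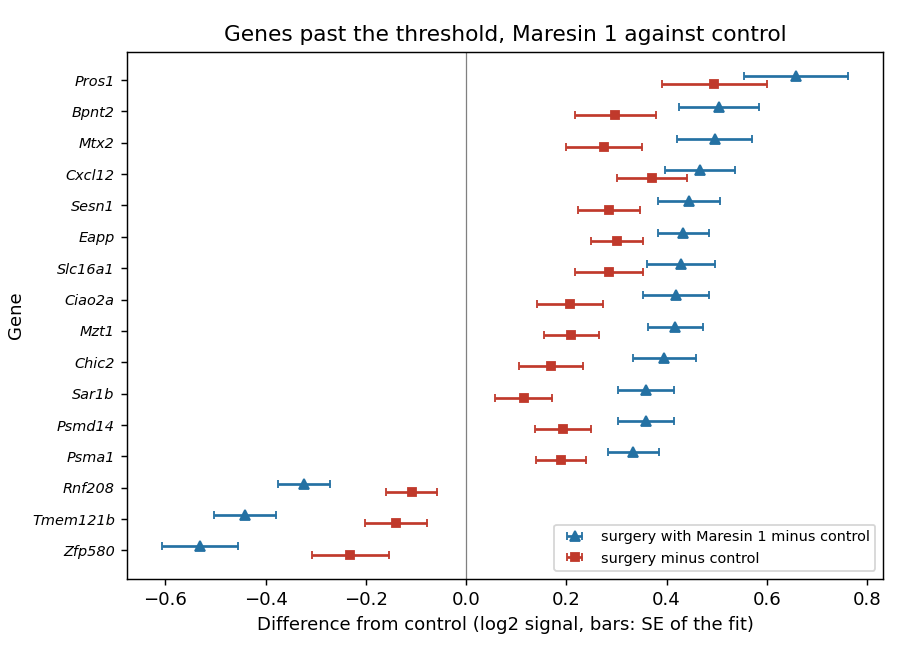
Difference from control (log2 signal) of the 16 genes called between Maresin 1 with surgery and control, with bars for the SE of the model, for Maresin 1 with surgery and for surgery alone. Both differences use the same control arrays, so values on one side of 0 do not by themselves show an effect of surgery (simulated data with no effect gave a correlation of 0.499 between them).

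Endothelial genes were higher than in control with Maresin 1 too, by a mean of 0.24, 15 of 17, with 9 passing when adjusted over the list alone and 0 over all genes (adjusted p = 1.6e-07, and adjusted p = 0.955 with an estimated correlation). Flt1 differed by 0.49, the angiopoietin receptor Tek by 0.49 and Abcb1a by 0.40, and the red cell gene Alas2 by 0.56 (adjusted p = 0.415). Pericyte and smooth muscle genes were higher by 0.12, 10 of 15, with 3 passing when adjusted over the list alone (adjusted p = 0.022, and adjusted p = 0.973 with an estimated correlation), a call lost without controls 2 and 3, control replicate 2 or Maresin 1 replicate 1, with the choroid plexus score as a covariate and on ranks. Interferon genes were higher by 0.15, 17 of 23, with 0 passing when adjusted over the list alone (adjusted p = 0.00318, and adjusted p = 0.955 with an estimated correlation). Gbp7 differed by 0.43 and Ifit2 by 0.37, and the call was lost without Maresin 1 replicate 1.

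Ribosomal protein genes were higher by 0.08, 71 of 83, with 7 passing when adjusted over the list alone (adjusted p = 3.5e-08, and adjusted p = 0.955 with an estimated correlation). Dentate granule genes were higher by 0.18, 15 of 17, with Trpc6 (0.50) and Dock10 (0.28) passing when adjusted over the list alone (adjusted p = 4.9e-05, and adjusted p = 0.955 with an estimated correlation), a call lost without control replicate 1. Both comparisons of Maresin 1 use the same Maresin 1 arrays. A list or gene with the same sign here as against surgery alone is therefore not independent evidence. That holds for small nucleolar RNA genes, Vgf and Synpo too. Myelinating oligodendrocyte genes were higher by 0.14, 14 of 15 (adjusted p = 0.00182, and adjusted p = 0.973 with an estimated correlation), a call lost without control replicate 3, without controls 2 and 3 (mean 0.03) and with the choroid plexus score as a covariate. The GABA and glutamate receptor list was higher by 0.07, 17 of 22, and Gabra4, a GABA-A receptor subunit gene, passed when adjusted over the list alone at 0.26 (adjusted p = 0.0178, and adjusted p = 0.955 with an estimated correlation). That call was lost in 9 of 22 alternatives, among them without control replicate 2, Maresin 1 replicate 3 or controls 2 and 3, with the choroid plexus score as a covariate, and with other scalings.

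Another 3 lists were lower with Maresin 1 than in control. Choroid plexus genes were lower by -1.81, all 21, with 19 passing when adjusted over the list alone (adjusted p = 8.4e-15, and adjusted p = 0.955 with an estimated correlation), and against control replicate 1 alone the mean difference was 0.19. Fibroblast genes were lower by -0.37, 16 of 20 (adjusted p = 0.0134, and adjusted p = 0.973 with an estimated correlation), and the mean was 0.14 against control replicate 1 alone. That call was also lost with the choroid plexus score as a covariate, without control replicate 2 or 3 and without Maresin 1 replicate 2 or 3. Small nucleolar RNA genes were lower by -0.14, 34 of 56 (adjusted p = 0.018, and adjusted p = 0.973 with an estimated correlation), a call lost without control replicate 2, Maresin 1 replicate 3 or controls 2 and 3, with the choroid plexus score as a covariate and on ranks. Gfap differed by 0.19 (SE 0.07, adjusted p = 0.330), Itgam by 0.24 (SE 0.09, adjusted p = 0.331) and Lcn2 by 1.65 (SE 0.80, adjusted p = 0.463, and from 1.10 without Maresin 1 replicate 3 to 2.31 without Maresin 1 replicate 1).

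With the 16 called genes included, 2160 had an unadjusted p under 0.05, 1104 higher and 1056 lower, and groups did not overlap for 14.3% of genes, against 10% by chance. Camera called 10 lists, fry 0 and the estimated correlation 0, while simulated data with no effect gave a median of 12.5 lists (5 to 23). That simulation has the limits given for surgery against control, and its count tests no single list. The calls lie close to the threshold: limma called 0 genes without control replicate 2, surgery replicate 3 or any 1 of the Maresin 1 arrays, 3 without surgery replicate 1, 2 without surgery replicate 2, and 245 without control replicate 1. That last fit leaves only the controls with high choroid plexus signal. The differences themselves moved little over 18 alternatives, from 0.40 to 0.46 for Eapp and from 0.57 to 0.73 for Pros1. Against control replicate 1 alone, with the spread taken from the other groups, the 16 lost their calls while their differences stood at 0.775 to 1.21 times those reported, and 4 other genes were called. These were Stoml3, Htra4, Tm4sf1 and Trpc6, named after their values were seen, and they rest on that 1 array, as for Stoml3 at 6.90 there against 7.54 and 7.69 in the other controls. Control replicate 1 is itself an extreme array. It had the highest median deposited signal and the lowest dentate granule (-0.29), ependymal (-0.41) and fibroblast (-0.33) scores of all arrays.

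Whether Maresin 1 turned the surgery values back was asked across all 18820 genes. With the surgery arrays held out in turn the slope of the Maresin 1 effect on the surgery effect was 0.0892, -0.0685 and -0.0794, a mean of -0.0196 ± 0.0944 (SD over the 3 held-out arrays). Simulated data with no reversal returned -0.011 and with full reversal -0.842, for effects with an SD of 0.3 over all genes, and noise brings the slope of smaller effects nearer to 0. The surgery differences here were mostly smaller than that, and no simulation used such sizes. The slope therefore cannot exclude a reversal. The plain correlation across genes, which are not independent replicates, was -0.305 with the surgery arrays shared, and simulated data with no effect gave -0.50. The effects of surgery and of Maresin 1 with surgery against control correlated at 0.740, against 0.499 in simulated data, and at -0.0525, 0.493 and 0.244 when each effect had its own controls. Without the 21 choroid plexus genes these last values were -0.0415, 0.369 and 0.0911.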

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

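Among the alternatives, scaling the linear values, the deposited values, other added constants, cyclic loess, the choroid plexus covariate and leaving out controls 2 and 3 were chosen after seeing the data. Over 18 of the alternatives, named genes were counted as unchanged 1858 times, with 209 calls lost, 48 gained and 81 values moved. For a gene called in neither fit, unchanged means a shift smaller than its SD within groups, whatever the sign. Reversal was counted only where a fit called the gene, and was found 0 times. Uncalled genes did change sign, as Lcn2 between Maresin 1 and surgery, from -0.96 to 1.00. Called lists kept their direction and call 519 times, lost the call 91 times and reversed 6 times. The endothelium, pericyte, interferon and reactive astrocyte lists of surgery against control kept their calls in 21 of 22 alternatives and lost them with an estimated correlation. Array signal over background limits the cytokine genes, of which 11 of 25 had a mean above the olfactory receptor level. Scaled to one median, the median of all genes differed by 0.10 between surgery and control, against 0.02 with quantile normalization, and camera compares lists with the other genes. Without controls 2 and 3, 1 control array remains and its spread is assumed to be that of the other groups. Where not stated, the cause was not tested.

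For surgery against control, called genes numbered 0 as reported, 67 with each array centred on its median (23 higher, 44 lower), 37 scaled to one median (12 and 25), 42 as deposited (1 and 41), 72 at an unadjusted p under 0.05 and 1.5-fold (13 and 59), and 0 to 169 leaving out 1 array. For Maresin 1 against surgery they numbered 1 when centred and 9 at an unadjusted p under 0.05 and 1.5-fold. For Maresin 1 against control, with 16 as reported (13 higher, 3 lower), there were 63 centred (11 and 52, 1 shared), 38 scaled (5 and 33, 1 shared), 43 as deposited (2 and 41, 0 shared), 50 without the lowest 50% (32 and 18, 15 shared, fewer genes tested), 91 at an adjusted p under 0.10 (58 and 33), 72 at an unadjusted p under 0.05 and 1.5-fold (10 and 62), and 4 higher with the covariate or without controls 2 and 3 (0 shared). They numbered 0 with a replicate block, without the variance trend, over every probe set, with the 6 compared arrays only and with a plain two-sample test without moderation, and 0 to 245 leaving out 1 array. The block has no ground in the data, since residuals of arrays with one number correlated at -0.24 to 0.055, with 0 of 9 pairs over 0.1. For surgery against control the smallest adjusted p by limma was 1.6e-77 as deposited and 5.9e-09 centred. For Maresin 1 against control it was 2.1e-79 and 4.2e-07. The counts as deposited thus depend on the variance prior rather than on the spread of each gene.

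Lists called between surgery and control numbered 22 centred, 23 scaled, 17 as deposited, 16 with the covariate, 18 without controls 2 and 3, 0 with an estimated correlation and 10 to 17 leaving out 1 array. Between Maresin 1 and surgery they numbered 23 centred, 24 scaled, 16 as deposited, 0 with an estimated correlation and 7 to 16 leaving out 1 array. Between Maresin 1 and control they numbered 16 without controls 2 and 3 and 0 with an estimated correlation. The slope was -0.2253 with shared surgery arrays, which pull it down by construction. Reversed without controls 2 and 3 were the choroid plexus list (0.139 after surgery, 0.191 with Maresin 1) and the fibroblast list with Maresin 1 (0.139, and 0.0938 with the covariate). The mean of the glucocorticoid list after surgery stayed positive (0.0649, and 0.0709 with the covariate) and turned only relative to the other genes.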

Other observations

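Some fixed lists were not yet described. After surgery, hypoxia and glycolysis genes were higher by 0.09, 19 of 23, with 0 passing when adjusted over the list alone (adjusted p = 0.00286, and adjusted p = 0.955 with an estimated correlation), among them the glucose carrier Slc2a1 at 0.24, and the call was lost without control replicate 2 or controls 2 and 3 and with the choroid plexus score as a covariate. Circadian clock genes were higher by 0.12, 12 of 16, with Ciart (0.60) and Arntl, a core activator of the clock, at -0.22 passing when adjusted over the list alone (adjusted p = 0.0195, and adjusted p = 0.955 with an estimated correlation), a call lost without control replicate 3, surgery replicate 2 or 3 or controls 2 and 3, and with the covariate. Glucocorticoid response genes were higher by 0.16, 19 of 26, with 0 passing when adjusted over the list alone (adjusted p = 0.0461, and adjusted p = 0.979 with an estimated correlation), a call lost in the same alternatives, without the lowest 30% of genes and on ranks. MicroRNA genes had a mean of -0.06 after surgery (adjusted p = 0.000993, and adjusted p = 0.955 with an estimated correlation) and 0.04 with Maresin 1 against surgery (adjusted p = 0.0207, and adjusted p = 0.955 with an estimated correlation). The former call was lost without control replicate 1 or 2, the latter without surgery replicate 3 or Maresin 1 replicate 3. Ependymal genes were higher with Maresin 1 than after surgery by 0.08, 14 of 16 (adjusted p = 0.0207, and adjusted p = 0.979 with an estimated correlation), a call lost without surgery replicate 1 or 3 or Maresin 1 replicate 1 or 2.

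Neuronal and immune groups gave small values. The synaptic plasticity list had a mean of -0.02 with Maresin 1 against surgery, 13 of 22 lower (adjusted p = 0.784). Between surgery and control it had a mean of -0.00 (adjusted p = 0.646), CA1 neurons 0.06 (0.447), interneurons 0.03 (0.719), activated microglia 0.02 (0.987), complement 0.05 (0.504) and monocytes and neutrophils 0.09 (0.217), by camera. Adjusted over the list alone, the neurogenesis genes Igfbpl1 (0.56) and Sox11 (0.34) were higher with Maresin 1 than in control, as was the alarmin gene Il33 (0.40), while Olig2, a factor of the oligodendrocyte lineage, was lower at -0.36. Stx1a, a presynaptic fusion gene, was lower with Maresin 1 than after surgery at -0.25, adjusted over its list alone. None of these 5 genes passed over all genes.

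Every test in the next paragraphs was chosen after the result was seen, except the splits of the arrays and the test of a technical axis, while the fits without each array were planned but put to this use afterwards. Choroid plexus transcripts were lower after surgery than in control. Choroid plexus tissue left on the hippocampus in controls 2 and 3 is a candidate explanation. The excess of each over control 1 had a similar profile across the 21 genes. For the log2 of the linear excess r was 0.9767, genes not being independent. For log2 differences, of control 2 from control 1 and of control 3 from the surgery mean, r was 0.974. The ratio of the excess in control 3 to that in control 2 ran from 0.447 to 2.34 between genes, with a median of 1.38. A shared profile is what left-over tissue needs, but any other cause that raised these genes in both arrays would give it too. An effect of surgery that lowers these genes would put control 1 above the 6 arrays of operated mice. It scored -0.78, below all of them (-0.68 to -0.53) and -0.2475 relative to the highest. Because 1 such control array decides nothing, an effect of surgery on these genes stays open.

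Endothelium, mural cell and interferon lists were higher after surgery than in control. With the choroid plexus score as a covariate the endothelium list stood at 0.2747, and the fibroblast list moved from -0.18 to 0.2986. That score varied within groups mainly among controls (SD 1.74, against 0.057 after surgery), so both values rest largely on control replicate 1. For the endothelium list, dilution by choroid plexus tissue in controls 2 and 3 is argued against only as far as that array goes. Its endothelium score was -0.18, against -0.16 and -0.17 in controls 2 and 3. One surgery array alone is argued against too, since each surgery array scored above every control for each list, though without surgery replicate 2 the interferon mean was 0.16 against 0.23 (largest adjusted p without a surgery array 0.0004496, at the preset correlation). Vessel-rich covering tissue may contribute, given that fibroblast value of 0.2986 after surgery, though control replicate 1 had the lowest fibroblast score of all arrays (-0.33). With Maresin 1 the fibroblast list stood at 0.0938 (adjusted p = 0.317) and the endothelium list at 0.245, both with the covariate, so a response of vessels to surgery also stays open, untested.

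Ribosomal protein and dentate granule transcripts were higher and small nucleolar RNA genes lower with Maresin 1 than after surgery. A technical axis within groups may underlie this. The correlation of the difference with the leading component of the residuals was 0.0624 in size, which the bound written beforehand would have taken as exclusion, but that bound was wrong, since choroid plexus genes lead this component (14 of 25) and the next one, with 20.9% of the residual variance, correlated at 0.290. A different share of dentate gyrus cannot be told apart from treatment, because the list score ranged over 0.4206 in the control arrays alone against a difference of 0.20, and the CA1 list differed the other way (-0.08). An effect of Maresin 1 stays open as well.

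Each comparison has only 10 splits of its 6 arrays, too few for a share under 0.05. For surgery against control the real split called 0 genes and the highest other 0, so that all 10 splits gave as many, and 10 lists against 19, with 9 splits giving as many. For Maresin 1 against surgery it called 0 genes against 1, with 10 splits as large, and 8 lists against 23, with 9 as large. For Maresin 1 against control it called 16 genes against 4, with 1 split as large, the real one, and 10 lists against 19, with 9 as large.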
